A study of Danio rerio with 18 samples.

How the data were processed

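RNA was measured by poly(A)-selected, strand-directional RNA sequencing in 18 libraries of zebrafish (Danio rerio), 3 in each of 6 groups, and each library came from a pool of 20 to 25 whole embryos, per the labels' protocols. At 24 hours post fertilisation (hpf) the groups were the wild-type WIK strain, a her3 knockout line, WIK embryos injected at the 1- to 4-cell stage with a her3 morpholino (an antisense oligomer that blocks a transcript's use), and WIK embryos injected with a mismatch morpholino as injection control. At 72 hpf the groups were WIK and the knockout line. The sample titles name the knockout line her3_38aa. Replicates were described by the submitters as biological, and each is a separate pool, so the p-values measure the spread between pools.

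The authors deposited 1 table of CPM values (reads of a gene scaled to a common effective library size) for 25535 genes. HISAT2 2.2.1, SAMtools 1.10, featureCounts 2.0.2, edgeR 3.34.0 and the danRer11 build are named in the submitters' processing notes, without their settings. The strand setting and the treatment of multi-mapping reads are not given in the sources used here, so genes with near-identical copies, such as the crystallins, her4 genes, globins and trypsin genes, and overlapping genes carry uncertain values. The CPM column of each library sums to between 912145 and 1206849, so the values were scaled to an effective library size and not to the plain total. Within each library 100.0% of the values were whole multiples of the worth of 1 read, within a tolerance of 0.01 reads. The reads recovered in this way numbered 14214136 to 23135995 per library, and 3 reads, the floor used for a gene at 0, corresponded to 0.122 to 0.255 CPM. Floors cover counting error only. Every gene in the deposited table had at least 15 reads in all and a read in at least 3 libraries, so genes below that level were not analysed here. Spike-in transcripts are mentioned in the protocol, and scaling to them was not analysed here.

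From these values log2(CPM + 0.5) was computed. A log2 difference and the 2-fold limit are on that scale, which understates the change of low genes. Where a group had 0 reads, the fold given is instead a ratio of mean CPM to a floor of 3 reads per library. Genes with at least 1 CPM in at least 3 libraries were tested, which kept 20738 and removed 4797. The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend and robust moderation) with 1 coefficient per group over all 18 libraries and 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05, and the number of called genes with at least a 2-fold difference is given beside the count. A log2 difference is given ± its standard error (SE) and a CPM level as mean ± SD with n = 3 libraries. The design foresaw a count test in place of this one for a table of raw counts. The table holds CPM, so limma on the log scale was used, and a fit of the recovered reads with limma's voom weights was added after the data were seen.

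Gene names came from the deposited identifiers through a table of symbols, which named 23539 of the 25535 genes. Many symbols in that table are of the human type in capitals, and 3433 genes share a symbol with another gene, in which case the Ensembl identifier is printed. her3 (ENSDARG00000076857) is listed there as HES3.

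A total of 28 gene lists was fixed before the data were examined, with 1123 symbols of which 1029 were matched. The lists reported cover the her, hes and hey family, the Notch pathway, proneural genes, neural progenitors, synaptic genes, myogenic regulators, muscle structure, matrix metalloproteinases and their inhibitors, rhabdomyosarcoma and cancer genes, the interferon response, inflammation and complement, leukocytes, erythroid cells, endothelium and heart, neural crest and pigment, lens and crystallins, photoreceptors, liver, pancreas and gut, skin, cartilage and bone, hatching gland and notochord, hox clusters, the cell cycle, heat shock and stress, the circadian clock, lipid and sterol metabolism, and retinoic acid; 1 further list, and some single genes, are not reported here. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists of a comparison, and again with an estimated correlation. fry tests whether a list's genes move on balance 1 way, and its mixed form whether they change in either direction. With an estimated correlation 0 lists passed in any comparison.

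The rule for named genes was also fixed before the data were examined. It took her3 first. For the 3 main comparisons it then took the 8 highest and 8 lowest log2 differences among genes with an adjusted p under 0.05, at least a 2-fold difference, the 3 values of 1 group above the 3 of the other and a mean of at least 1 CPM in the higher group, with clone-named genes left out. For the other comparisons it took the 3 highest and 3 lowest, and for each list up to 4 called members with the largest differences. Examples printed from the lists were picked, after the data were seen, from those members whose call held with each library left out in turn, unless a loss is stated. In group-against-group comparisons, named genes other than her3 and list members therefore had 1 group's 3 libraries above the other's 3. No such separation was required for the interaction and the knockout minus morpholino effect.

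Called genes were counted near her3 with the order of genes in the GRCz12tu assembly. It is another build than the authors', so it served only to find neighbours and no coordinate is printed. The shares were compared with Fisher's exact test, 2-sided, in a family of 10 tests. Overlaps of calls were compared with the number given by independent lists and tested with Fisher's exact test, 2-sided.

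The limma procedure was tested on data simulated for the knockout comparison at 24 hpf, with 20761 genes. Of these 200 were changed 2-fold or 4-fold, and a list of 40 others was shifted by less. It recovered 68% of the genes changed 2-fold and 94% of those changed 4-fold, with 8 calls outside the changed and shifted genes. The simulated genes were independent, with the same spread in every group and no library that stood apart. The simulation therefore does not show how many calls are false in the real data. Alternatives covered the pseudocount, the filter, the scaling, the libraries in the fit, a replicate block, the moderation, array weights and each library left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.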

Results

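Poly(A) RNA was compared between zebrafish embryos of a her3 knockout line, embryos injected with a her3 morpholino and their controls. her3 encodes a Hairy/E(spl)-related transcriptional repressor of the neural plate. There were 6 groups of 3 libraries: WIK, her3 knockout, her3 morpholino and mismatch morpholino at 24 hpf, and WIK and her3 knockout at 72 hpf. The 18 libraries held 14214136 to 23135995 recovered reads, with the lowest total in WIK_24hpf replicate 1. Within 4 groups 1 library stood apart from the other 2. The chi-square per degree of freedom between replicates was 27.67 and 31.86 for pairs with WIK_24hpf replicate 1 and 4.26 for the remaining pair. It was 18.45 and 29.02 against 5.23 for her3_MO_24hpf replicate 1, 28.31 and 20.08 against 4.59 for mm_MO_24hpf replicate 3, and 10.41 and 6.11 against 3.76 for her3_KO_72hpf replicate 3. The lowest value of any pair of replicates was 3.64, and all 18 libraries were kept.

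The her3 transcript was higher, not lower, in the libraries labelled knockout and in those labelled her3 morpholino. At 24 hpf it stood at 10 ± 0.916 CPM in WIK, 22.1 ± 0.0623 CPM in the knockout-labelled libraries, 35.9 ± 5.15 CPM with the her3 morpholino and 7.87 ± 0.214 CPM with the mismatch morpholino (SD, n = 3). At 72 hpf it was 1.35 ± 0.114 CPM in WIK and 2.15 ± 0.313 CPM in the knockout-labelled libraries. The log2 difference of knockout-labelled from WIK was 1.11 ± 0.12 at 24 hpf (adjusted p = 1.1e-05) and 0.51 ± 0.12 at 72 hpf (adjusted p = 0.010). The second call was lost without WIK_72hpf replicate 2 (adjusted p = 0.052), without her3_KO_72hpf replicate 1 (0.056), with only the compared groups in the fit (0.052) and with voom (0.097). With the her3 morpholino the log2 difference was 2.11 ± 0.12 from the mismatch morpholino (adjusted p = 5.9e-08) and 1.79 ± 0.12 from WIK (adjusted p = 4.3e-07). The mismatch morpholino and WIK differed by -0.33 ± 0.12, which did not pass the test (adjusted p = 0.090). A transcript level does not show whether protein was made. The labels therefore have no check here in the direction a loss of transcript would give, and every direction below follows the labels. The titles name the knockout line her3_38aa, and what its allele does to the transcript was not tested.

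**Figure D1:**
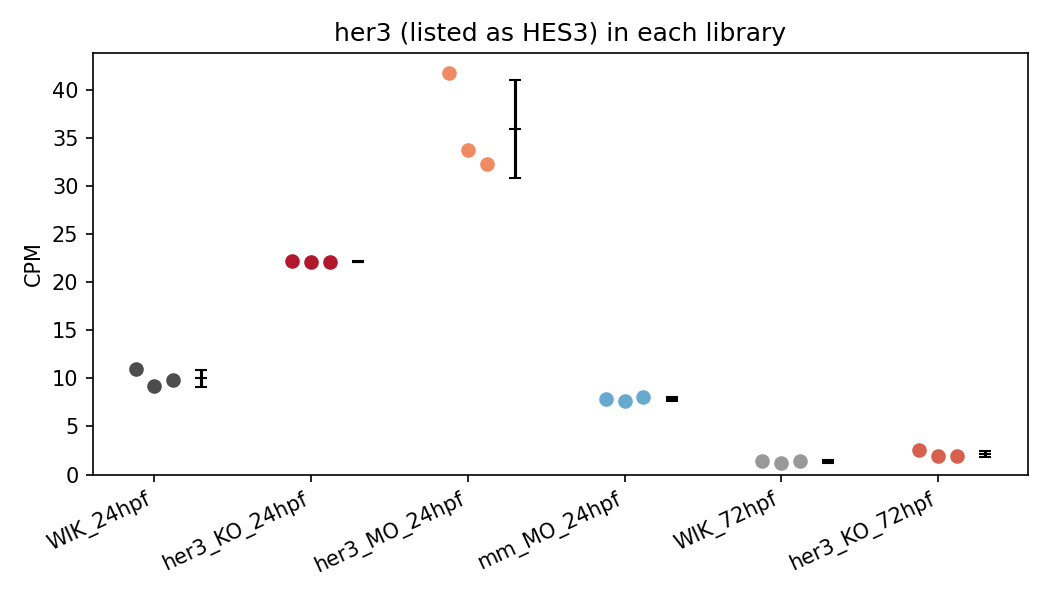
CPM of her3, listed as HES3, in each of the 18 libraries (points) by group, with the mean ± SD of 3 libraries beside them. The knockout-labelled libraries at 24 hpf lay at 22.1 ± 0.0623 CPM, above the 10 ± 0.916 CPM of WIK, and the her3 morpholino libraries at 35.9 ± 5.15 CPM.

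The knockout line was compared with WIK at 24 hpf to find what changes in embryos of that line early in development. Genes of several unrelated functions differed most. Among those lower in the knockout-labelled libraries were malb, a MAL-family membrane protein, mhc2dgb of the class II histocompatibility complex, apcs, a pentraxin, SIRT5, a mitochondrial deacylase, CSRP1 (ENSDARG00000030980), a LIM-domain protein, ANXA3, a calcium-dependent phospholipid-binding annexin, and TCP11L2. Among those higher were pde11al, of the cyclic nucleotide phosphodiesterase family, ADGRB1 (ENSDARG00000078529), an adhesion receptor, alox5b.3, a lipoxygenase gene, cfap221, a cilium-associated gene, igldcp, and 3 genes of the actin cytoskeleton, nebl, TMOD3 and PDLIM3 (ENSDARG00000011023). malb stood at 0.265 ± 0.045 CPM against 9.57 ± 2.13 in WIK, a log2 difference of -3.70 ± 0.20 (adjusted p = 5.7e-09). ANXA3 fell from 47.3 ± 3.16 to 5.55 ± 0.267 CPM, a log2 difference of -2.98 ± 0.12 (adjusted p = 3.5e-10). The log2 differences were -3.29 ± 0.23 for mhc2dgb, -3.27 ± 0.36 for apcs, -3.23 ± 0.16 for TCP11L2, -3.15 ± 0.30 for SIRT5 and -3.11 ± 0.28 for CSRP1. apcs was also lower than WIK with the mismatch morpholino. pde11al rose from 0.212 ± 0.0827 to 11.2 ± 2.48 CPM, a log2 difference of 4.03 ± 0.23 (adjusted p = 1.3e-08). igldcp had 0 reads in the 3 WIK libraries and 7.16 ± 2.56 CPM in the knockout-labelled ones, at least 37.9-fold higher when set against a floor of 3 reads per library. ADGRB1 rose by 3.24 ± 0.15, nebl by 3.19 ± 0.14, alox5b.3 by 3.13 ± 0.18, TMOD3 by 3.09 ± 0.27, cfap221 by 2.72 ± 0.21 and PDLIM3 by 2.67 ± 0.31 on the log2 scale. mtbl, at -3.29 ± 0.99 (adjusted p = 0.039), held its call only without WIK_24hpf replicate 2 and lost it without each of the other 5 libraries in turn, with the highest adjusted p, 0.19, without WIK_24hpf replicate 1.

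In all, 2620 of 20738 tested genes were called at 24 hpf, 1246 higher and 1374 lower, and 604 of them differed at least 2-fold. The largest of the 216 clone-named genes that met the rule for named genes had log2 differences of 3.64 and -4.75. The count was 906 with only the compared groups in the fit, and it was 1523 without her3_KO_24hpf replicate 1 and 1700 without her3_KO_24hpf replicate 3. Without WIK_24hpf replicate 1 it was 2079, and 1762 of the 2620 genes (67.3%) were still called.

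Lens genes formed the list with the lowest camera p at 24 hpf, and all of its called members were lower in the knockout-labelled libraries. Of 44 crystallin and other lens genes 20 fell, 0 rose and 24 did not pass (23 fell adjusted over the list alone; camera adjusted p = 1.2e-08, and adjusted p = 0.89 with an estimated correlation). The lens channel gene MIP (ENSDARG00000013963) fell by 1.08 ± 0.18 on the log2 scale and the crystallin gene crygm2d7 by 1.74 ± 0.36. Without WIK_24hpf replicate 1, 12 lens genes fell and the camera adjusted p was 2.6e-07. Proneural genes and neural progenitor genes also had a lower balance, with 5 and 6 lower, 0 and 0 higher and 30 and 30 not passed (5 and 9 lower adjusted over the list alone; camera adjusted p = 0.0055 and 0.0038, and adjusted p = 0.89 for both with an estimated correlation). The neuronal differentiation factors NEUROD1 and NEUROD6 (ENSDARG00000020794) fell by 0.56 ± 0.11 and 1.27 ± 0.14 on the log2 scale, the retinal homeobox gene rx2 by 0.53 ± 0.12, and the fatty acid binding protein gene FABP7 (ENSDARG00000034650) by 1.26 ± 0.18. In the heat shock and stress list 5 genes fell, 1 rose and 36 did not pass (6 and 1 adjusted over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.89 with an estimated correlation). The immediate-early genes ATF3 and FOSL1 fell by 1.45 ± 0.25 and 2.05 ± 0.42, while the chaperone gene HSPA8 (ENSDARG00000037403) rose by 1.83 ± 0.27. The WIK libraries were split for these immediate-early genes: FOSL1 stood at 26.5, 6.18 and 31.3 CPM and ATF3 at 50.3, 19.9 and 54.6 CPM in WIK_24hpf replicates 1, 2 and 3. The list mean of replicate 2, 0.07, lay within the knockout-labelled values of 0.05, 0.11 and 0.02, and those of replicates 1 and 3 were 0.44 and 0.38.

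Inflammation and complement genes had 6 lower, 0 higher and 24 not passed (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.045, and adjusted p = 0.91 with an estimated correlation), among them the prostaglandin synthase gene PTGS2 (ENSDARG00000010276), at 4.53 ± 0.856 against 39.3 ± 23.3 CPM, with 44.3, 13.9 and 59.7 CPM in WIK replicates 1, 2 and 3. PTGS2 was also lower than WIK with both morpholinos. The list mean was 0.03 in WIK replicate 2, below the knockout-labelled values of 0.08, 0.06 and 0.07, and 0.46 and 0.7 in WIK replicates 1 and 3. In the liver, pancreas and gut list 7 fell, 0 rose and 35 did not pass (7 adjusted over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.91 with an estimated correlation), with the fibrinogen chain FGG at 57.1 ± 0.894 against 131 ± 11.7 CPM. Among matrix metalloproteinases and inhibitors 2 rose, 0 fell and 22 did not pass (2 adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.89 with an estimated correlation). They were MMP14 (ENSDARG00000008388), a membrane-bound collagenase, at 28.7 ± 1.36 against 7.94 ± 0.533 CPM, and its partner TIMP2 (ENSDARG00000075261), at 26.9 ± 1.55 against 19.5 ± 0.215 CPM. The metalloproteinase list mean of WIK_24hpf replicate 3, -0.04, lay within the range of the knockout-labelled libraries, and those of replicates 1 and 2 were -0.49 and -0.29. Without WIK_24hpf replicate 1 these 6 lists other than lens did not pass (2 inflammation and 2 liver genes fell), with camera adjusted p of 0.065 for proneural genes, 0.058 for neural progenitors, 0.065 for heat shock, 0.12 for inflammation, 0.065 for liver and 0.21 for metalloproteinases. Without the 4 libraries that stood apart the proneural (0.051), heat shock (0.072), inflammation (0.17) and metalloproteinase (0.17) lists did not pass.

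The other lists did not pass camera at 24 hpf with all libraries. In the her, hes and hey family 3 rose, 5 fell and 20 did not pass (3 and 7 adjusted over the list alone; camera adjusted p = 0.20), with her4.4, a Notch-responsive gene, lower by -0.79 ± 0.10 and the segmentation clock gene her7 higher by 0.94 ± 0.20. Among Notch pathway genes 1 rose and 0 fell of 22, NOTCH1 (ENSDARG00000052094) at 52.8 ± 7.26 against 22.0 ± 10.5 CPM. Of 29 myogenic regulators 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.12), with the paraxial mesoderm genes tbx6 and msgn1 higher by 1.04 ± 0.20 and 0.86 ± 0.16. In the rhabdomyosarcoma and cancer list 5 rose and 2 fell of 53 (camera adjusted p = 0.12), with the receptor gene ERBB2 and HRAS (ENSDARG00000098497) higher by 1.3 ± 0.27 and 0.71 ± 0.09. Neural crest and pigment genes had 2 higher and 10 lower of 38 (camera adjusted p = 0.13): crestin, a neural crest marker, rose by 0.91 ± 0.14 while the pigment genes TYRP1 (ENSDARG00000056151) and pnp4a fell by 0.60 ± 0.08 and 0.90 ± 0.16. Counts higher and lower were 1 and 1 of 13 for interferon, 3 and 3 of 23 for leukocytes, 1 and 1 of 27 for erythroid genes, and 1 and 1 of 32 for endothelium and heart. They were 3 and 5 of 56 for muscle structure, 2 and 4 of 38 for skin, 3 and 1 of 40 for cartilage and bone, 1 and 0 of 23 for hatching gland and notochord, 1 and 0 of 48 for hox clusters, and 3 and 2 of 53 for photoreceptors. They were 1 and 3 of 61 for the cell cycle, 2 and 4 of 36 for the circadian clock, 1 and 6 of 39 for lipid and sterol metabolism, 1 and 2 of 28 for retinoic acid, and 0 and 0 of 41 for synaptic genes. Adjusted over the list alone the counts higher and lower were 2 and 2 for interferon, 4 and 3 for leukocytes, 1 and 0 for erythroid genes, 0 and 1 for endothelium and heart, 3 and 6 for muscle structure, 2 and 5 for skin, 0 and 0 for hox clusters, 1 and 2 for the cell cycle, 4 and 4 for the circadian clock, 0 and 2 for retinoic acid and 3 and 10 for neural crest and pigment. They stayed as given above for the other lists of this paragraph. The medians of the cell cycle (-0.02) and circadian (0.01) lists changed sign with the scaling, and camera leaned the other way than the median in both. The interferon list had a median of -0.08 and a mean of 0.03, and the photoreceptor median was 0. The counts higher and lower without WIK_24hpf replicate 1 were 3 and 1 for the her, hes and hey family, 1 and 5 for neural crest and pigment, 4 and 2 for myogenic regulators, 3 and 2 for the cancer list, 1 and 3 for muscle structure, 4 and 2 for skin, 0 and 3 for the circadian clock and 2 and 1 for leukocytes. They were 4 and 0 for cartilage and bone, 1 and 0 for interferon, erythroid and retinoic acid genes, 2 and 1 for endothelium and heart, and 2 and 0 for hatching gland and notochord. Cartilage and bone genes (13 higher, 1 lower) passed camera upwards without the 4 libraries that stood apart, and neural crest and pigment genes (2 higher, 11 lower) downwards, at adjusted p = 0.032 and 0.039, and adjusted p = 0.94 for both with an estimated correlation. The counts then were 9 and 3 for myogenic regulators, 10 and 5 for skin, 5 and 9 for muscle structure, 6 and 2 for endothelium and heart, 5 and 0 for hox clusters and 5 and 2 for retinoic acid. They were 3 and 7 for lipid and sterol metabolism, 4 and 5 for the circadian clock, 3 and 4 for the cell cycle, 3 and 0 for hatching gland and notochord, 2 and 0 for synaptic genes and 1 and 1 for the Notch pathway.

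**Figure D2:**
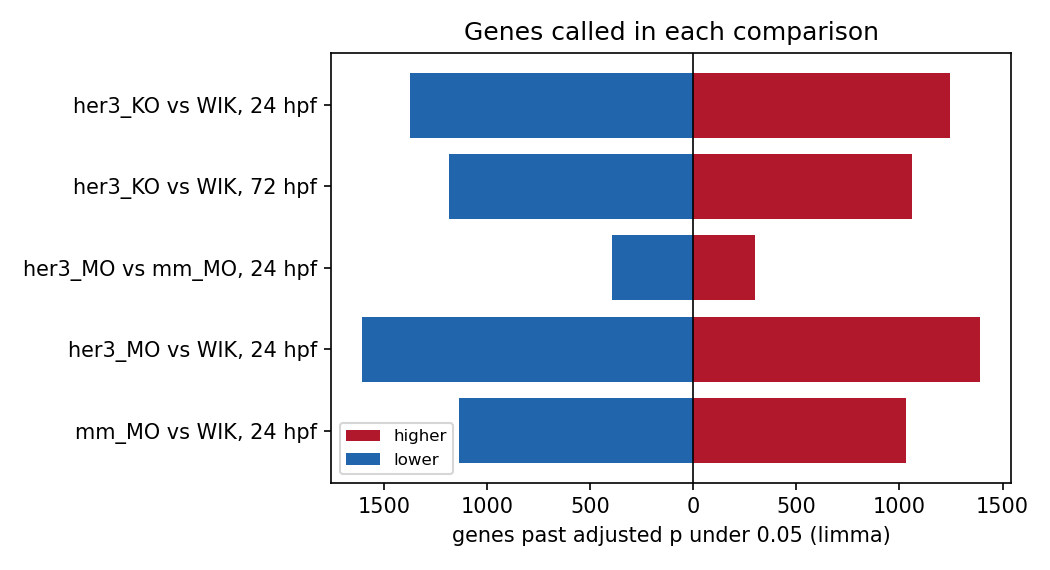
Number of genes past an adjusted p of 0.05 (limma) in 5 comparisons, higher to the right and lower to the left of 0. The her3 morpholino against the mismatch morpholino had 301 higher and 393 lower genes, fewer than the 1246 and 1374 of the knockout-labelled libraries against WIK at 24 hpf.

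Called genes were more frequent near her3 in the knockout-labelled libraries at 24 hpf. Within 5 Mb of it 29 of 101 tested genes were called at 24 hpf (28.7%), against 12% elsewhere (Fisher's exact test, odds ratio 2.95, 95% interval 1.84 to 4.60, p = 7.9e-06, adjusted p = 4e-05). On the chromosome of her3 the share was 18.2% against 11.9% (odds ratio 1.65, exact p = 3.4e-06, adjusted p = 3.4e-05). At 72 hpf the odds ratio was 1.51 for the chromosome (exact p = 0.00033, adjusted p = 0.0011) and 1.37 within 5 Mb (exact p = 0.26, adjusted p = 0.32). For the her3 morpholino against the mismatch morpholino it was 1.61 for the chromosome (exact p = 0.013, adjusted p = 0.026) and 2.31 within 5 Mb (exact p = 0.040, adjusted p = 0.067). For the her3 morpholino against WIK, embryos of the same strain, 25.7% of the genes within 5 Mb were called against 14.6% elsewhere (odds ratio 2.03, 95% interval 1.24 to 3.22, exact p = 0.0042, adjusted p = 0.010), and the chromosome did not pass (odds ratio 1.2, adjusted p = 0.12). For the mismatch morpholino against WIK, also of that strain, neither passed (odds ratio 1.28 within 5 Mb and 1.1 for the chromosome, adjusted p = 0.44 for both).

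At 72 hpf the knockout-labelled libraries were compared with WIK to see which genes differ later in development. The light-responsive clock repressor PER2 rose, and 3 trypsin genes of the exocrine pancreas fell. SIRT5, malb, TCP11L2, igldcp, TMOD3 and cfap221 were again among the largest differences. PER2 stood at 59.3 ± 4.87 CPM against 7.26 ± 0.893 in WIK, a log2 difference of 2.95 ± 0.13 (adjusted p = 6e-10). lonrf1 rose from 11 ± 0.558 to 69.9 ± 2.5 CPM, a log2 difference of 2.61 ± 0.08 (adjusted p = 2.8e-12). The mitochondrial transhydrogenase gene nnt2 rose by 3.12 ± 0.20, cfap221 by 3.05 ± 0.21, TMOD3 by 2.84 ± 0.27, rusf1 by 2.67 ± 0.37 and the DNA polymerase gene POLL by 2.55 ± 0.12 on the log2 scale. igldcp had 0 reads in WIK and 5.29 ± 1.22 CPM in the knockout-labelled libraries, at least 34.7-fold higher against the floor of 3 reads per library. SIRT5 fell from 11.2 ± 0.730 to 0.564 ± 0.531 CPM, a log2 difference of -3.57 ± 0.30 (adjusted p = 8.1e-07). The log2 differences were -3.11 ± 0.20 for malb, -2.99 ± 0.16 for TCP11L2, -2.89 ± 0.20 for the nucleotidase gene ENTPD6, -2.83 ± 0.24 for the phospholipase gene pla2g4f.1, -2.76 ± 0.16 for the splicing factor SMNDC1, -2.60 ± 0.24 for the translation factor subunit EIF3B (ENSDARG00000074213) and -2.53 ± 0.16 for the zinc finger gene znf1124.

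A total of 2245 genes was called at 72 hpf, 1060 higher and 1185 lower, and 494 of them differed at least 2-fold. Among 179 clone-named genes that met the rule the extreme log2 differences were 3.25 and -5.38. The count was 3528 with only the compared groups in the fit and 4645 without the 4 libraries that stood apart, and it was 1418 without WIK_72hpf replicate 2 and 1451 without her3_KO_72hpf replicate 2.

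Of 36 circadian clock genes 16 rose, 1 fell and 19 did not pass at 72 hpf (16 and 2 adjusted over the list alone; camera adjusted p = 9.2e-10, and adjusted p = 0.15 with an estimated correlation; fry adjusted p = 8.2e-06). Besides PER2, the clock repressors CRY1 (ENSDARG00000045768) and NR1D1 rose from 17.7 ± 1.11 to 71.2 ± 5.92 CPM and from 12.4 ± 1.06 to 46.1 ± 10.3 CPM, and the activator BMAL1 (ENSDARG00000035732) fell from 13.0 ± 1.46 to 3.97 ± 1.06 CPM. In the liver, pancreas and gut list 10 fell, 0 rose and 32 did not pass (11 and 1 adjusted over the list alone; camera adjusted p = 2e-05, and adjusted p = 0.73 with an estimated correlation). The trypsin genes prss59.1, prss59.2 and prss1 fell by 2.04 ± 0.29, 1.90 ± 0.21 and 1.84 ± 0.25 on the log2 scale. WIK_72hpf replicate 1 lay with the knockout-labelled libraries for this list, at a mean of -0.81 against -0.87, -0.69 and -1.07, while WIK_72hpf replicates 2 and 3 were at -0.16 and -0.19. For prss59.1 it had 3.81 CPM against 12.3 and 11.1 in the other WIK libraries and 1.74, 2.01 and 1.14 in the knockout-labelled ones. In the skin list 8 fell, 0 rose and 30 did not pass (12 and 1 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.73 with an estimated correlation), with the keratin krt15 at 92.7 ± 16.1 against 217 ± 9.77 CPM. Of 53 photoreceptor genes 7 fell, 2 rose and 44 did not pass (9 and 2 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.73 with an estimated correlation), with PRPH2 (ENSDARG00000014840), an outer segment disc protein, at 21.9 ± 5.27 against 42.5 ± 5.29 CPM. The list mean of her3_KO_72hpf replicate 3, 2.97, lay within the WIK values of 2.95, 3.12 and 2.99. Of 61 cell cycle genes 9 rose, 2 fell and 50 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 0.00032, and adjusted p = 0.73 with an estimated correlation), with cyclin CCNE2 higher by 0.58 ± 0.08 and the spindle gene dlgap5 lower by -1.49 ± 0.22. For the cell cycle list her3_KO_72hpf replicate 3, at a mean of -1.19, lay within the WIK_72hpf values of -1.24, -1.15 and -1.24. Muscle structure genes passed camera (adjusted p = 0.022, and adjusted p = 0.73 with an estimated correlation) with a median of -0.22, although 1 of 56 fell and 0 fell adjusted over the list alone. Cell cycle genes had 32 higher and 2 lower without the 4 libraries that stood apart (camera adjusted p = 5e-07), and 18 photoreceptor, 14 skin and 10 muscle structure genes fell while 4, 4 and 2 rose. With an estimated correlation these lists had adjusted p = 0.81, 0.81, 0.81 and 0.82. Without WIK_24hpf replicate 1 alone, which enters only the shared spread, 16 cell cycle genes rose. Erythroid genes lay at the threshold with all libraries, with 4 higher and 0 lower of 27 (camera adjusted p = 0.05 after rounding, and adjusted p = 0.73 with an estimated correlation). Without the 4 libraries 11 were higher and 1 lower (camera adjusted p = 0.001, and adjusted p = 0.81 with an estimated correlation). They had 6 higher and 0 lower without WIK_24hpf replicate 1 (camera adjusted p = 0.038, and adjusted p = 0.78 with an estimated correlation).

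Among the lists that did not pass at 72 hpf, stress genes went both ways, with 8 higher and 4 lower of 42 (camera adjusted p = 0.26). The immediate-early gene FOS rose from 6.96 ± 0.242 to 42.8 ± 7.66 CPM. Of 30 inflammation genes 8 rose and 4 fell (camera adjusted p = 0.81): PTGS2 (ENSDARG00000010276) and the cytokine feedback gene SOCS3 (ENSDARG00000025428) rose by 1.73 ± 0.34 and 1.99 ± 0.30, and hamp, the iron hormone hepcidin, fell by 1.83 ± 0.18. The mean of that list was 0.02 and its median -0.12. In the her, hes and hey family 3 rose and 2 fell of 28 (camera adjusted p = 0.75), with BHLHE40 and her4.2 higher by 0.91 ± 0.07 and 0.75 ± 0.09 and her4.4 lower by -0.97 ± 0.10. Of 38 neural crest and pigment genes 5 rose and 2 fell (camera adjusted p = 0.25), and crestin rose by 2.03 ± 0.14. Proneural genes went both ways, with 4 higher and 3 lower of 35 and a median of 0.14 (camera adjusted p = 0.22), and neurog1 and ascl1b were among those that fell, by 0.80 ± 0.15 and 0.77 ± 0.09. In the her, hes and hey family 5 rose and 3 fell without WIK_24hpf replicate 1, and among proneural genes 6 rose and 5 fell. These were 7 and 1, and 8 and 5, without the 4 libraries that stood apart.

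The effects of the knockout label at the 2 ages were compared, and the pairs of groups share no library. Of the called genes 315 were higher at both ages against 63.7 for independent lists (Fisher's exact test, p = 4.4e-140), and 393 were lower at both against 78.5 (exact p = 2.3e-181). Another 69 were called in opposite directions, against 141.4. The deviations of WIK_24hpf replicate 1 and her3_KO_72hpf replicate 3 from their groups had r = -0.426. The former is subtracted in its effect and the latter added, so they push the 2 effects the same way. The p-values therefore do not measure a shared effect of the label alone. Across the 20738 genes, which are not independent replicates, the log2 differences had r = 0.35. At least 2-fold in the same direction at both ages were 188 genes. A difference of the effect between ages was called for 963 genes, 518 with a higher value at 72 hpf and 445 with a lower one. PER2 and PTGS2 (ENSDARG00000010276) had interaction log2 differences of 3.42 ± 0.19 and 4.49 ± 0.48, the latter with WIK_24hpf libraries at 44.3, 13.9 and 59.7 CPM, and pde11al and ADGRB1 of -3.69 ± 0.33 and -2.99 ± 0.21. Without the 4 libraries that stood apart 2237 genes were called. The count was 559 without her3_KO_24hpf replicate 1, 605 without her3_KO_24hpf replicate 3, 589 without her3_KO_72hpf replicate 2, 617 without WIK_72hpf replicate 2 and 626 without WIK_72hpf replicate 3.

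**Figure D3:**
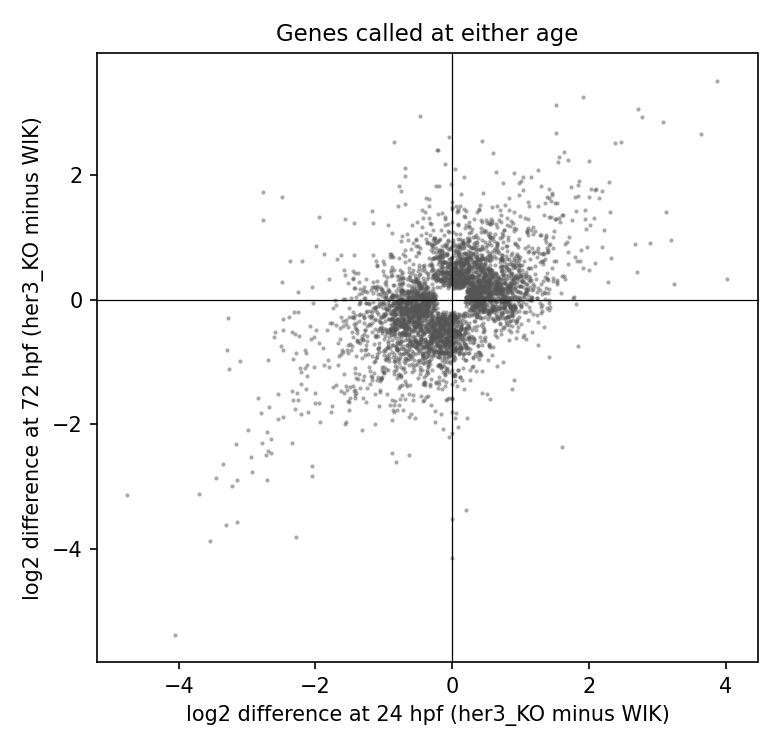
Log2 difference of the knockout-labelled libraries from WIK at 24 hpf (x axis) and at 72 hpf (y axis), 1 point per gene called at either age. The 708 genes called in the same direction at both ages lie in the upper right (315) and lower left (393) parts.

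The her3 morpholino was compared with the mismatch morpholino, the injected control of the series. Among the genes that rose were 3 of melanin synthesis, DCT and the TYRP1 pair. The largest rises were in dbndd1, grinab, the receptor gene PAQR3 (ENSDARG00000017703), the plexin plxnb2a.2, a receptor for semaphorins, the Pim-related kinase pimr55, HES3, chico and mhc2dgb. The largest falls were in ms4a17a.7, the finTRIM gene ftr06, the kinesin KIF16B (ENSDARG00000080018), the microtubule-binding EML5, sccpdha.2, the organic cation transporter slc22a3, the helicase DHX57 and the centromere gene CENPS. dbndd1 rose from 0.448 ± 0.192 to 8.05 ± 1.28 CPM, a log2 difference of 3.18 ± 0.35 (adjusted p = 5e-05), and chico from 9.94 ± 0.746 to 41.9 ± 2.72 CPM, a log2 difference of 2.02 ± 0.13 (adjusted p = 2e-07). The log2 differences were 2.45 ± 0.24 for grinab, 2.28 ± 0.20 for PAQR3, 2.28 ± 0.24 for plxnb2a.2, 2.2 ± 0.22 for pimr55 and 1.96 ± 0.23 for mhc2dgb, which was lower in the knockout-labelled libraries. ms4a17a.7 fell by 2.13 ± 0.25, ftr06 by 2.13 ± 0.15, KIF16B by 1.91 ± 0.20, EML5 by 1.80 ± 0.26, sccpdha.2 by 1.65 ± 0.18, slc22a3 by 1.64 ± 0.21 and DHX57 by 1.62 ± 0.13. CENPS, at -1.58 ± 0.39 (adjusted p = 0.036), lost its call without each of the 3 her3_MO_24hpf libraries in turn and without mm_MO_24hpf replicate 2, with the highest adjusted p, 0.17, for the last. EML5 lost its call with only the compared groups in the fit (adjusted p = 0.056).

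In this comparison 694 genes were called, 301 higher and 393 lower, and 168 of them differed at least 2-fold. Among 64 clone-named genes that met the rule the extremes were 3.84 and -3.70. The count was 182 with only the compared groups in the fit and 2678 without the 4 libraries that stood apart, 327, 373, 422 and 441 without her3_MO_24hpf replicate 2, mm_MO_24hpf replicate 2, her3_MO_24hpf replicate 3 and mm_MO_24hpf replicate 1 in turn.

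Of 38 neural crest and pigment genes 5 rose, 0 fell and 33 did not pass (9 rose adjusted over the list alone; camera adjusted p = 2.7e-05, and adjusted p = 0.20 with an estimated correlation). The melanin synthesis genes DCT, TYRP1 (ENSDARG00000029204) and TYRP1 (ENSDARG00000056151) stood at 122 ± 7.33 against 86.6 ± 10.3, 65.2 ± 3.77 against 41.8 ± 4.31 and 145 ± 5.31 against 107 ± 11 CPM. Hatching gland and notochord genes had 3 lower, 0 higher and 20 not passed (6 lower adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.23 with an estimated correlation). None of the 3 is a hatching enzyme gene: they were ENTPD5, the matrix gene epyc and the notochord factor tbxta, at -0.76 ± 0.18, -0.79 ± 0.17 and -0.47 ± 0.12, and each lost its call without her3_MO_24hpf replicates 2 and 3 and mm_MO_24hpf replicates 1 and 2 in turn, ENTPD5 also without mm_MO_24hpf replicate 3. The highest adjusted p values were 0.15 without her3_MO_24hpf replicate 3, and 0.083 and 0.18 without her3_MO_24hpf replicate 2. Lens genes had a median of 0.31 and passed camera upwards (adjusted p = 0.00064, and adjusted p = 0.86 with an estimated correlation), although 0 rose and 1 of 44 fell. The lens mean of mm_MO_24hpf replicate 3, -0.85, lay with the her3_MO_24hpf values of -0.93, -0.89 and -0.85. Those of mm_MO_24hpf replicates 1 and 2 were -1.29 and -1.21. Camera was also passed downwards by muscle structure (0 higher and 1 lower of 56, adjusted p = 0.0097), lipid and sterol metabolism (0 and 1 of 39, 0.0098), liver, pancreas and gut (0 and 2 of 42, 0.017) and erythroid genes (0 and 1 of 27, 0.019). It was passed upwards by the cell cycle (1 and 0 of 61, 0.0061) and the Notch pathway (2 and 0 of 22, 0.027). For these 6 lists the adjusted p with an estimated correlation was 0.86 for muscle, 0.23 for lipid, 0.86 for liver, 0.86 for erythroid, 0.86 for cell cycle and 0.83 for Notch genes. Without the 4 libraries that stood apart 36 of 56 muscle structure genes fell (camera adjusted p = 1.4e-20), 9 neural crest and pigment genes, 7 lens genes and 6 cell cycle genes rose, and 9 hatching gland and notochord genes fell. With an estimated correlation these lists had adjusted p = 0.33, 0.33, 0.65, 0.78 and 0.33. For muscle structure the groups overlapped with all libraries: list means were -0.27, -0.84 and -1.1 in her3_MO_24hpf replicates 1, 2 and 3 and -0.45, -0.41 and -0.83 in the mm_MO_24hpf ones, so the libraries left out, her3_MO_24hpf replicate 1 and mm_MO_24hpf replicate 3, were those against the fall. In the fit without WIK_24hpf replicate 1, 9 neural crest and pigment, 3 lens and 4 cell cycle genes rose, 2 muscle structure and 2 erythroid genes fell, and 1 lipid gene rose and 2 fell. The lipid (camera adjusted p = 0.41), liver (0.84), erythroid (0.84) and Notch (0.49) lists did not pass without the 4 libraries, while 7 lists that had not passed did. Upwards these were skin (15 higher, 2 lower, camera adjusted p = 2.9e-06) and leukocyte genes (2 and 1, 0.028), and downwards hox (0 and 11, 2.9e-06), myogenic (0 and 9, 0.00026), synaptic (0 and 9, 0.003), cartilage and bone (5 and 16, 0.013) and proneural genes (0 and 6, 0.028). In that order they had adjusted p = 0.52, 0.61, 0.52, 0.33, 0.65, 0.73 and 0.73 with an estimated correlation. Of single list members, the scavenger receptor marco of macrophages rose by 1.55 ± 0.18, and PER2, CRY1 (ENSDARG00000045768), MMP14 (ENSDARG00000008388) and the heme synthesis gene PPOX fell by 0.82 ± 0.13, 0.70 ± 0.09, 0.78 ± 0.13 and 1.2 ± 0.15.

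Both injected groups were compared with uninjected WIK to see which genes differ between injected and uninjected embryos. A difference of clutch or parents between the pools was not tested, so it cannot be told apart from injection. Some hox genes, which pattern the body axis, fell with either morpholino, as did the Notch-responsive her4.5, and some lens genes rose. Of 48 hox genes 24 and 19 fell and 0 and 0 rose (29 and 30 lower and 1 and 1 higher adjusted over the list alone; camera adjusted p = 2e-10 and 1.6e-11, and adjusted p = 0.35 and 0.54 with an estimated correlation). HOXB7 fell by 0.83 ± 0.16 with the her3 morpholino, and HOXD9 and HOXC12 (ENSDARG00000103133) fell by 0.64 ± 0.15 and 0.70 ± 0.14 with the mismatch morpholino. Hox genes lower numbered 8 and 7 without WIK_24hpf replicate 1, and without the 4 libraries that stood apart 32 and 12. In the her, hes and hey family 11 and 9 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.00013 and 2.8e-05, and adjusted p = 0.35 and 0.54 with an estimated correlation), with the Notch-responsive her4.5 lower by -0.77 ± 0.15 and -0.94 ± 0.15. In the former comparison 1 member rose, her3 itself. The counts lower were 7 and 7 without WIK_24hpf replicate 1. The list mean of her3_MO_24hpf replicate 1, 0.37, lay within the WIK values of 0.6, 0.4 and 0.35, and those of replicates 2 and 3 were 0.12 and 0.13. Of 44 lens genes 21 and 4 rose and 0 fell (28 and 7 adjusted over the list alone, with 1 and 0 lower; camera adjusted p = 7.7e-09 and 0.00048, and adjusted p = 0.35 and 0.68 with an estimated correlation). The lens counts were 24 and 7 higher without WIK_24hpf replicate 1.

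Muscle and neural progenitor lists also passed downwards in both injected groups. Muscle structure genes had 0 and 1 higher and 22 and 11 lower of 56 with the her3 and the mismatch morpholino (camera adjusted p = 6.3e-09 and 8.7e-05, and adjusted p = 0.42 and 0.68 with an estimated correlation). Their list mean in her3_MO_24hpf replicate 1, -0.27, lay within the WIK values of -0.33, -0.23 and -0.35. Neural progenitor genes had 0 and 1 higher and 12 and 12 lower of 36 (camera adjusted p = 1e-04 and 8.7e-05, and adjusted p = 0.35 and 0.54 with an estimated correlation). Circadian genes had 0 and 2 higher and 13 and 9 lower of 36 (0.00031 and 0.024, and adjusted p = 0.35 and 0.68 with an estimated correlation), and WIK_24hpf replicate 1, at a mean of -0.56, lay with the injected libraries (-0.57 to -0.42), apart from -0.27 and -0.21 in the other WIK libraries. Stress genes had 6 and 4 higher and 17 and 9 lower of 42 (0.00084 and 0.027, and adjusted p = 0.35 and 0.68 with an estimated correlation). Inflammation genes had 2 and 0 higher and 8 and 10 lower of 30 (0.0059 and 0.0015, and adjusted p = 0.53 and 0.68 with an estimated correlation). In both lists WIK_24hpf replicate 2, at 0.07 and 0.03, lay within the range of the injected libraries.

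With the her3 morpholino hatching gland and notochord (0 higher and 6 lower of 23, camera adjusted p = 0.00038), liver, pancreas and gut (0 and 2 of 42, 0.0014), erythroid (1 and 7 of 27, 0.0023), cartilage and bone (0 and 9 of 40, 0.02) and endothelium and heart genes (3 and 6 of 32, 0.04) passed downwards. Leukocyte (10 and 2 of 23, 0.0076) and neural crest and pigment genes (10 and 1 of 38, 0.014) passed upwards. In that order they had adjusted p = 0.35, 0.55, 0.55, 0.55, 0.53, 0.35 and 0.35 with an estimated correlation. With the mismatch morpholino cell cycle genes passed downwards (1 and 7 of 61, 0.007) and lipid and sterol metabolism upwards (6 and 0 of 39, 0.007), with adjusted p = 0.68 and 0.54 with an estimated correlation.

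The fit without WIK_24hpf replicate 1 ended the calls of endothelium and heart with the her3 morpholino (camera adjusted p = 0.083) and of stress with the mismatch one (0.25). Counts higher and lower with the her3 morpholino were then 0 and 4 for muscle structure, 0 and 7 for neural progenitors, 3 and 10 for stress, 0 and 4 for inflammation, 0 and 0 for hatching gland and notochord, 0 and 1 for liver, 1 and 2 for erythroid, 0 and 4 for cartilage and bone, 8 and 1 for leukocyte and 5 and 0 for neural crest and pigment genes. With the mismatch morpholino they were 0 and 4 for muscle structure and 0 and 4 for inflammation. Myogenic regulators then passed downwards for both (0.019 and 0.031), and leukocyte (0.02) and photoreceptor genes (0.014) upwards for the mismatch morpholino, with adjusted p = 0.61, 0.63, 0.63 and 0.63 with an estimated correlation.

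In the fit without the 4 libraries that stood apart the her3 morpholino lost the liver (camera adjusted p = 0.27), erythroid (0.39), inflammation (0.27) and endothelium and heart lists (0.23), and the mismatch morpholino the stress list (0.11). Gained with the her3 morpholino were myogenic (0 higher and 12 lower, 6.3e-05), synaptic (0 and 10, 0.039) and proneural genes (2 and 5, 0.048) downwards and skin (14 and 1, 0.0012) upwards, with adjusted p = 0.17, 0.59, 0.59 and 0.39 with an estimated correlation. Counts higher and lower moved to 0 and 47 for muscle structure, 3 and 16 for cartilage and bone, 1 and 10 for hatching gland and notochord and 9 and 3 for neural crest and pigment genes. With the mismatch morpholino they moved to 3 and 14 for the cell cycle and 1 and 4 for inflammation.

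With the her3 morpholino against WIK 2997 genes were called, 1391 higher and 1606 lower, 335 of them at least 2-fold. With the mismatch morpholino against WIK 2171 were called, 1034 higher and 1137 lower, 340 of them at least 2-fold. LNX1, an E3 ubiquitin ligase, RBL2, of the retinoblastoma family, and RSPO1, a Wnt agonist, had the highest differences in both, at 2.49 ± 0.20, 2.57 ± 0.16 and 2.60 ± 0.18 with the her3 morpholino and 2.72 ± 0.20, 2.97 ± 0.16 and 2.93 ± 0.18 with the mismatch one. The lowest were cox6b1, ALPP and PTGS2 (ENSDARG00000010276) with the her3 morpholino, at -2.67 ± 0.14, -2.55 ± 0.30 and -2.38 ± 0.34. With the mismatch morpholino they were irg1l, PTGS2 and apcs, at -3.10 ± 0.71, -3.01 ± 0.34 and -2.64 ± 0.36. irg1l lost that call without WIK_24hpf replicate 1 (adjusted p = 0.060), and its WIK_24hpf libraries stood at 44, 3.54 and 97.1 CPM. Both comparisons use the same WIK libraries, and no overlap between them was tested. For the mismatch morpholino against WIK another split of the same 6 libraries into 3 and 3 gave 2986 calls, more than the real 2171. With only the compared groups in the fit the counts were 70 and 154. For the her3 morpholino the count was 1291 without WIK_24hpf replicate 1, 5254 without WIK_24hpf replicate 3, 1022 without her3_MO_24hpf replicate 2 and 1343 without her3_MO_24hpf replicate 3. For the mismatch morpholino it was 1048 without mm_MO_24hpf replicate 2 and 1305 without mm_MO_24hpf replicate 1, and 3399 without the 4 libraries that stood apart.

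**Figure D4:**
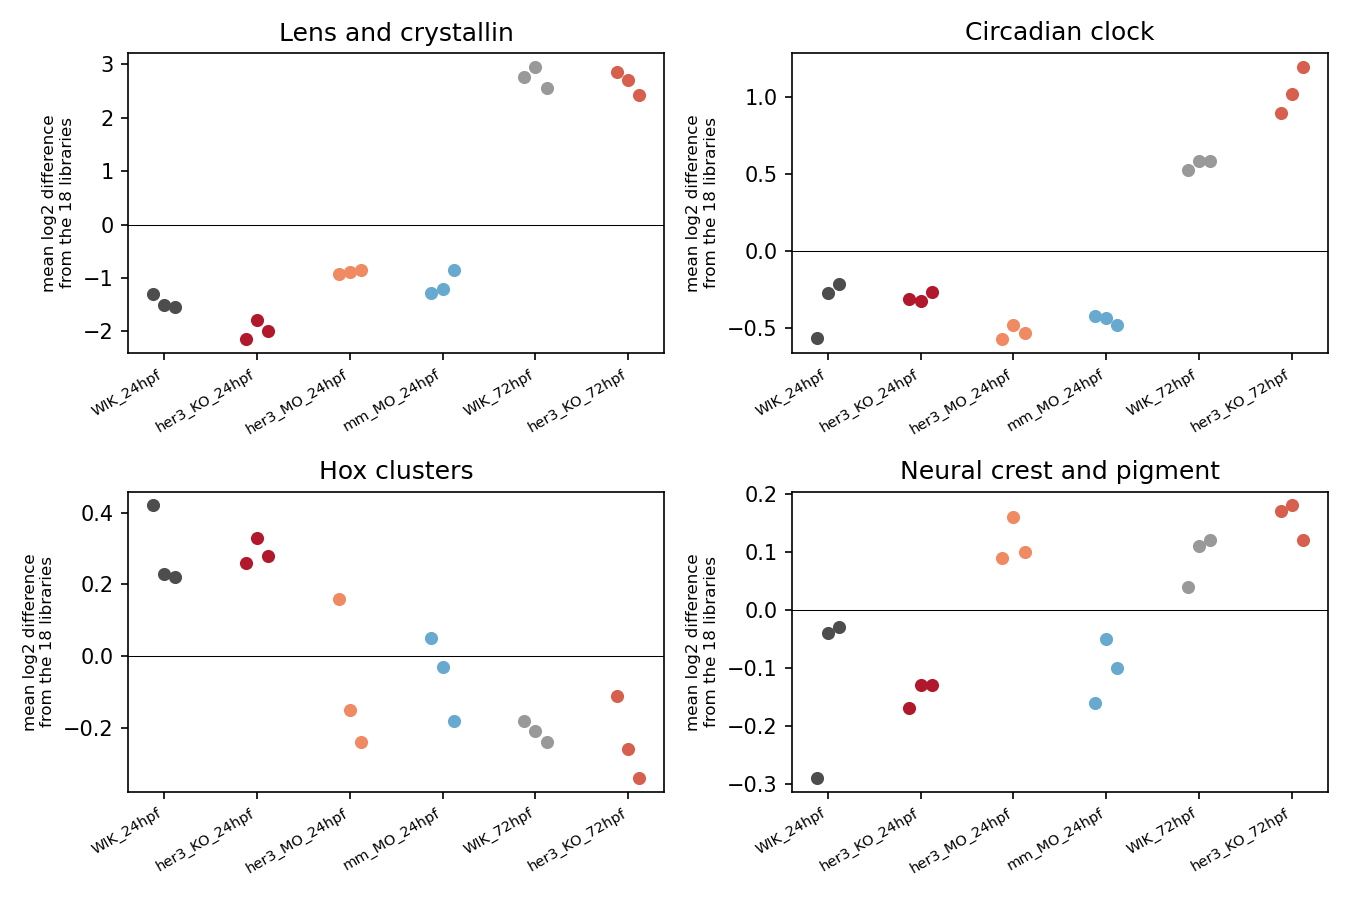
Mean log2 difference of a list's genes from their mean over the 18 libraries (y axis), 1 point per library, by group, for the lens, circadian, hox, and neural crest and pigment lists. The 3 knockout-labelled libraries at 24 hpf lie lowest for lens genes (-2.15, -1.78 and -2.00) and those at 72 hpf highest for circadian genes (0.90, 1.02 and 1.2).

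The knockout and morpholino effects at 24 hpf, which share no library, were set against each other to see whether both ways of targeting her3 move the same genes. Of the genes called in both, 61 were higher in both against 18.1 for independent lists (Fisher's exact test, p = 3e-17) and 84 lower in both against 26.0 (exact p = 3.8e-22). A further 143 were called in opposite directions, against 43.6, an excess that was not tested. The deviations of WIK_24hpf replicate 1 and mm_MO_24hpf replicate 3 from their groups had r = 0.685. Both libraries are controls, so their deviations push the 2 effects the same way. Independent lists are therefore not a sound reference here, and the p-values do not measure agreement. Across the 20738 genes r was 0.08. Over the genes called for the knockout label it was -0.06, and -0.15 over those that differed at least 2-fold. A difference between the effects was called for 1589 genes, 801 higher and 788 lower for the knockout label. mhc2dgb, grinab and apcs had the lowest differences, -5.24 ± 0.32, -5.01 ± 0.35 and -4.94 ± 0.50, and pde11al and alox5b.3 the highest, 4.71 ± 0.33 and 4.11 ± 0.26. igldcp came next, and no fold is given for it because WIK had 0 reads. apcs was also lower with the mismatch morpholino than in WIK, so part of its difference lies between the controls. The count was 981 with only the compared groups in the fit and 3759 without the 4 libraries that stood apart.

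Between 24 and 72 hpf in WIK, a cone opsin gene and a muscle enzyme gene rose and hatching gland genes fell. The ultraviolet cone opsin OPN1SW had 0 reads at 24 hpf and 944 ± 72.3 CPM at 72 hpf, at least 5000-fold higher against the floor of 3 reads per library. AMPD1, the AMP deaminase of muscle, rose from 0.108 ± 0.0587 to 588 ± 45.3 CPM. The hatching gland protease gene ctslb fell from 784 ± 168 to 0.234 ± 0.160 CPM, ctslb.4 from 1340 ± 304 to 1.71 ± 0.0900 CPM, and afp4 (ENSDARG00000041490) from 1090 ± 318 to 0.551 ± 0.316 CPM. Of 20738 genes 15455 were called, 7995 higher and 7460 lower, and 8422 differed at least 2-fold.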

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

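The tests of WIK_24hpf replicate 1 and of clock phase below were chosen only after the result was seen; the others were written down earlier. The effect of the knockout label differed between 24 and 72 hpf for 963 genes by a tested interaction (limma, adjusted p under 0.05). Among named genes the interaction log2 differences, 72 hpf minus 24 hpf, were -3.69 for pde11al, -2.99 for ADGRB1 (ENSDARG00000078529), -2.34 for CDH15, -2.24 for nebl, -1.78 for EIF3B (ENSDARG00000074213), -1.77 for PDLIM3 (ENSDARG00000011023) and -1.72 for alox5b.3. They were 0.90 for ANXA3, 1.60 for nnt2, 2.12 for POLL, 2.13 for CSRP1 (ENSDARG00000030980), 2.16 for apcs, 2.66 for lonrf1, 2.99 for mhc2dgb, 3.42 for PER2, 4.05 for irg1l and 4.49 for PTGS2 (ENSDARG00000010276). The irg1l call held without WIK_24hpf replicates 2 and 3 and was lost without each of the other 10 of the 12 libraries in turn, with the highest adjusted p, 0.081, without WIK_24hpf replicate 1. irg1l stood at 44, 3.54 and 97.1 CPM in WIK_24hpf replicates 1, 2 and 3, and PTGS2 at 44.3, 13.9 and 59.7 CPM. PTGS2 was also lower than WIK at 24 hpf with both morpholinos, and irg1l and apcs with the mismatch morpholino. Their differences at 24 hpf are therefore not particular to the knockout label. The CDH15 call held without WIK_24hpf replicates 2 and 3 and her3_KO_72hpf replicates 1 and 3 and was lost without each of the other 8, with the highest, 0.095, without her3_KO_72hpf replicate 2.

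With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was 1 of the 10 with as many calls, itself, for the knockout label at 24 hpf (2620 genes, highest other split 0), at 72 hpf (2245, highest other 1), for the her3 morpholino against the mismatch morpholino (694, highest other 469), for the her3 morpholino against WIK (2997, highest other 1) and for age in WIK (15455, highest other 1). For the mismatch morpholino against WIK 2 of the 10 splits gave as many, the real one with 2171 and another with 2986, which put WIK_24hpf replicate 1 and mm_MO_24hpf replicate 3 on the same side, and so points to a structure of the samples. The deviations of these 2 libraries from their groups had r = 0.685. For the interaction 2 of 100 splits gave as many calls as the real 963, a share under 0.05. Splits that mix the labels also move the genotype difference of each age into the spread, which lowers their counts. The share therefore cannot exclude chance for the interaction itself. The other split, with 3402, exchanges the labels at 1 age as a whole and so adds the effects of both ages. For the knockout effect minus the morpholino effect 2 of 100 splits gave as many as the real 1589, with the same limit. The other split, with 2198, put mm_MO_24hpf replicate 3 with her3_MO_24hpf replicates 2 and 3, again along the libraries that stood apart.

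The first pattern is the number of genes called between knockout-labelled and WIK libraries at 24 hpf. A large difference in developmental stage would line the effect up with the change from 24 to 72 hpf. Across genes r with that axis was -0.029 (-0.069 over the called genes), which argues against a large shift along it. A small offset near 24 hpf cannot be excluded in this way, because genes that change shortly around that age need not follow the axis. The lists that passed went both ways. Lens and proneural genes rose with age in WIK and were lower in the knockout-labelled libraries, the direction of a delay. Metalloproteinase genes also rose with age but were higher. Liver, inflammation and heat shock genes fell with age and were lower, against a delay. WIK_24hpf replicate 1 as the only source is argued against as well, since 67.3% of the called genes were called without that library. Variants linked to her3 in the knockout line may contribute, with an odds ratio of 2.95 for calls within 5 Mb and 1.65 on the chromosome, and they cannot be told apart from other sources of calls near her3, since the pairs with no line difference went apart: within 5 Mb the odds ratio was 2.03 for the her3 morpholino against WIK (adjusted p = 0.010), 2.31 for it against the mismatch morpholino (0.067) and 1.28 for the mismatch morpholino against WIK (0.44), and on the chromosome 1.2 (0.12), 1.61 (0.026) and 1.1 (0.44). Loss of her3 function and any other difference between the line and WIK are confounded in this design.

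The second pattern is the set of genes called between the her3 and the mismatch morpholino. A difference in developmental stage may contribute: across genes r with the stage axis was 0.106, and 0.036 over the called genes, and it cannot be told apart at that size. An effect of her3 remains untested beside it. The transcript was higher in the her3 morpholino libraries, and a transcript level does not show whether protein was made.

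The third pattern is the rise of circadian genes in knockout-labelled libraries at 72 hpf. A shift in clock phase, as from another collection time or light, may account for it if activators move against repressors. The 5 activator genes had a median log2 difference of -0.09, with 3 below 0 and 1 called, while the 16 per, cry and nr1d genes had a median of 0.67, with 1 below 0 and 10 called. The collection time and light of each group are not given in the sources used here, so a phase shift cannot be told apart from an effect of the genotype on the clock.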

How the results depend on the processing

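The fits without the 4 libraries that stood apart, with voom weights on the recovered reads and with gene-by-gene array weights were chosen after seeing the data. For the comparisons in the order her3_KO_24hpf and her3_KO_72hpf against their WIK, her3_MO against mm_MO, her3_MO and mm_MO against WIK, interaction, and knockout minus morpholino, the counts were 2620, 2245, 694, 2997, 2171, 963 and 1589. With the libraries of the compared groups only they moved to 906, 3528, 182, 70 and 154 for the first 5 and 981 for the last. The count rose at 72 hpf and fell in the others listed, so fewer libraries alone do not account for it. The groups differed in spread: the chi-square per degree of freedom between replicates reached 31.86 in WIK_24hpf and 4.48 in WIK_72hpf. The main fit shares 1 spread per gene over all groups, so calls between groups of wider spread may be too many. With array weights they were 8007, 7296, 12834, 12615, 13902, 6290 and 9848, from an estimate that stopped before it converged (weights 0.0634 to 44.6), and 4354, 6045, 5749, 6253, 5542, 3380 and 5024 with the gene-by-gene estimate (0.0930 to 4.16). Without the 4 libraries that stood apart they were 4645 for her3_KO_72hpf, 2678 for her3_MO against mm_MO, 3399 for mm_MO against WIK, 2237 for the interaction and 3759 for knockout minus morpholino; the cause was not tested. With each library left out in turn the counts ranged from 1523 to 3394, 1418 to 1663, 327 to 817, 1022 to 5254, 1048 to 2943, 559 to 1228, and 1126 to 1869, and for age from 14614 to 15670. The other settings, with pseudocounts of 0.1 and 1, no filter, a filter at 5 CPM, median-of-ratios and quantile scaling, no trend and no robust moderation, and voom, kept each of these counts within 1.5-fold. At least 2-fold, 188 genes (708 at any size) were called in the same direction at both ages and 6 in opposite directions; for knockout and morpholino 24 (145) were called in the same direction and 35 in opposite ones, against 2.4 for independent lists. Lists past camera numbered 7, 6, 10, 15 and 11 in the 5 comparisons and 0 in each with an estimated correlation. The 6 at 72 hpf leave out the erythroid list, whose camera adjusted p was 0.05 after rounding. fry passed 1 at 72 hpf, 3 for the her3 against the mismatch morpholino and 6 for the mismatch morpholino against WIK. For the knockout label at 24 hpf it passed the neural progenitor, metalloproteinase, cancer, lens and stress lists, each at adjusted p = 0.048. The her3 morpholino against WIK had the most lists past fry, among them hox (adjusted p = 0.01), lens (0.013), muscle structure (0.034) and circadian genes (0.0052).

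With the replicate number as a block the counts were 2410, 2078, 611, 2820, 2013, 836 and 1412, and 15352 for age. The numbers do not pair the samples: in no comparison were the correlations of same-numbered libraries all over 0.1 (-0.16, -0.23 and 0.14 for the first). In her3_KO_72hpf against WIK_72hpf and in her3_MO against mm_MO each library correlated best with its own number, which is a hint only.

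Of 488 values of named genes 266 lost their call with the compared groups only, 54 with voom, 49 without the 4 libraries, 38 without trend and robust moderation, 37 with quantile scaling, 32 with the block and 14 or fewer with each other setting that kept all libraries. The losses with the compared groups only were 87 of 101 for her3_MO and 80 of 99 for mm_MO against WIK. They were 32 of 60 for her3_MO against mm_MO, 59 of 105 for her3_KO_24hpf and 7 of 102 for her3_KO_72hpf. Of 3012 values with 1 library left out 663 lost their call. Direction turned in 2: krt8 with the her3 morpholino against WIK, at 0.06 with quantile scaling (adjusted p = 0.63), and irg1l in the same comparison, at 0.20 with array weights (adjusted p = 0.74). Quantile scaling moved the median of all genes by -0.267 for age, and no other scaling moved one by over 0.1. The tests near her3 at 2-fold are void, since under 80% of those genes had a place. The planned edgeR and DESeq2 fits were not run, although whole reads were recovered, and voom on those reads was fitted instead. Scaling to spike-ins was not run, because no spike-in values were used here. Low depth limits genes near 3 reads, or 0.122 to 0.255 CPM.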

Other observations

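Further genes of the fixed lists differed at 72 hpf in the knockout-labelled libraries. The interferon-induced isg15 fell by 1.5 on the log2 scale, the endothelial receptor tek by 0.78 and the hatching enzyme he1.1 by 1.36, while BTG2, an antiproliferative gene, rose by 0.97. Each of these calls held with each library left out in turn.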
